A study of Drosophila melanogaster with 3 samples.

How the data were processed

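The data were chromatin immunoprecipitation with sequencing (ChIP-seq) peak lists from whole Drosophila melanogaster embryos of both sexes, 8 to 24 h old. The fly line carried a transgene for CG4328, a LIM-homeodomain transcription factor gene, fused at its C-terminus to green fluorescent protein (GFP). Chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP, per the labels. The labels give 1 group of 3 biological replicates, so no treated group is compared with a control group, and no control library was analysed here. The age was taken from the source name, because another age label held a value that is not an embryo age.

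There were 10 peak lists, 5 for each of 2 genome builds (dm6 and dm3). In each build there was a relaxed list per replicate, a relaxed list from the 3 replicates pooled, and an "optimal" list thresholded by the irreproducible discovery rate (IDR). Per the text notes deposited with each library, each replicate list was made from that replicate's alignments and a control, the pooled list from the alignments of all 3, and the optimal list from these relaxed lists, which hold peaks together with background. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. The deposited signal value of each peak was assigned by the authors' pipeline on a scale that is not stated, so it was used only to rank peaks within a list. The deposited −log10 q value is the authors' significance of each peak and was used only to describe the lists. No read counts or library totals were used, so the depth of each library is unknown, and no interval here covers read-counting error. The Wilson intervals (95%) cover only the number of peaks.

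The optimal dm6 list was compared with the pooled relaxed dm6 list record by record. All 3688 optimal peaks were among the 3688 pooled peaks of highest signal value (100%). The lowest optimal signal value was 130.9 and the highest among pooled peaks with no overlap to an optimal peak was 130.8. The list is thus a truncation of the pooled ranking, and support for a peak in each replicate was not a criterion for that peak. The same held for all 3593 optimal peaks in dm3. The dm6 list held 9 repeated intervals, and all records were kept. The 3688 peaks merge into 3443 separate regions that cover 1433768 bp.

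Positions were annotated in dm6 with the release 6 genome sequence and the BDGP 6.54 gene models (Ensembl release 115), restricted to 13945 protein-coding genes on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X. All dm6 peaks lay on these arms and within their reference lengths. No dm3 annotation was used, and no coordinate was converted between builds. Coordinates are 1-based. A summit within 500 bp of an annotated transcription start was classed as promoter. The remaining summits were classed as exon, as intron (within a gene body but no exon) or as intergenic, in that order. Each summit was assigned to the gene with the nearest transcription start, which need not be a gene it regulates.

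Replicate support was the share of optimal peaks that overlapped, by at least 1 bp, a peak among the 3688 highest of a replicate's own list. As a scale for it, the optimal peaks were placed at random 1000 times on their own chromosome arms; this is no independent test, because the optimal list was called from the same libraries. Rank agreement was Spearman's rho and Pearson's r of log2 signal value across shared peaks, without a p-value, because peaks are not independent replicates. Classes and chromosome arms were compared with the 25262 pooled peaks that did not overlap an optimal peak ("relaxed-only" peaks), by 2-sided Fisher's exact tests. Gene lists were tested against 10000 random lists of equal size matched on decile of the length of genome nearest to each gene's starts (2-sided permutation p; smallest possible 0.0002). Motifs on either strand were sought within 100 bp of each summit and in windows of the same size centred 500 bp to each side. The difference was tested with 100000 sign-flip permutations (2-sided; smallest possible p 1e-05). Motif presence against signal value was tested by Spearman's rho with 100000 permutations. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Peaks and genes are the units of these tests, so the p-values do not measure spread between embryo collections, and neighbouring peaks are not fully independent.

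The groups, designs, 21 gene lists, 24 motifs and most alternatives were set before the data were examined. The lists held 793 different genes, 19 of them in more than 1 list. Of their symbols, 3 were matched through a synonym, and 3 were not matched and are not analysed here. A further 5 lists were made after the peaks had been seen. Named genes followed a rule fixed in advance: CG4328 and the other LIM-homeodomain genes; the nearest gene of each of the 20 highest peaks; in each list up to 4 members with the highest peak and up to 2 members without a peak, in alphabetical order; and the 10 genes nearest to the most peaks. Not every gene the rule selects is named.

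Alternatives included summits within 100 bp or a reciprocal overlap of 50% as the criterion for a shared peak, longer replicate lists, only the 1844 highest optimal peaks, the dm3 lists, other promoter windows (200 and 1000 bp), other backgrounds, other gene assignments, other motif windows and flanks, and leaving out each replicate. Because the optimal list was deposited only for the 3 replicates together, leaving out a replicate means that only optimal peaks overlapping a top peak of both other replicates were used. The replicate left out still contributed to the optimal list and its ranking. This filter may also favour peaks of high signal value, so a call gained or lost under it cannot be credited to that replicate. Comparison of motif windows at equal GC count (Mantel-Haenszel odds ratio with a normal-approximation p), use of only peaks supported by all 3 replicates, and the checks of the 5 later lists were chosen after the data had been seen.

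The tests were tested on simulated data. For gene lists, 2% of 100 lists without an effect and 100% of 100 lists of 40 genes with a 3-fold effect were called, over 13945 genes. For motifs, 0% of 20 sets without an effect and 100% of 20 sets with TAATTA written into 5% of 3688 windows were called. In these sets, which of the 3 windows of a relaxed-only peak was called the summit was drawn at random. They thus held no difference in base composition between summits and flanks, and the 0% does not cover calls that come from such a difference. For classes, 3% of 100 sets without an effect and 100% of 100 sets with an odds ratio of 1.5 were called, with a mean recovered odds ratio of 1.49. For support, 82.1% was recovered in 1 run where 80% had been planted. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.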

Results

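CG4328-GFP occupancy was profiled by anti-GFP ChIP-seq in whole embryos collected from 8 to 24 h, in 3 biological replicates of 1 group. The dm6 optimal list held 3688 peaks with a median width of 450 bp. Each relaxed dm6 list, from replicate 1, 2 or 3 or from the pool, held 30000 peaks. Median widths in the replicate lists were 430, 456 and 396 bp. No records were identical between any pair of replicate lists, and read depth was not known for any library. All positions below are in dm6.

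The tagged gene itself was examined first. CG4328 (FBgn0036274, 3L, 12290956 to 12296123, minus strand) had 0 optimal peaks in its body or nearest to its starts, and the closest optimal summit lay 13352 bp outside the gene, at a peak ranked 2683 that was nearest to INPP5E. In the relaxed lists, replicate 3 held 7 peaks in or nearest to CG4328, the highest ranked 4073 of 30000, the pooled list held 3 with a best rank of 17418, and replicates 1 and 2 held 0. The 6 other LIM-homeodomain genes examined, Awh, Lim1, Lim3, Lmx1a, ap and tup, which encode developmental transcription factors of the same class, also had no optimal peak nearest to them. Among them, tup, the Islet homologue, had the closest optimal summit, 1728 bp outside the gene at a peak ranked 502 and nearest to CG10602. With 0 of 7 LIM-homeodomain genes against 2.08 expected from matched random lists, the difference did not pass the permutation test (adjusted permutation p = 0.269). As 0 is the lowest possible count and gave an unadjusted permutation p of 0.167, no shortage of peaks in a list this short could have passed.

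The highest peaks lay at genes of many functions. The highest, with a deposited signal value of 3256.3, was at 3L 19590401 to 19590821, with its summit 87 bp upstream of CG14100, and ranked 2, 3 and 1 in replicates 1, 2 and 3. The next, at 2L 6612405 to 6612932, had its summit in an intron 1019 bp downstream of a start of CG11050 and ranked 1, 1 and 3. It was followed by peaks 35 bp upstream of Ugalt, a UDP-galactose transporter gene (X, 2703675 to 2704083), in an intron 2329 bp from the nearest start of Tlk, the Tousled-like kinase gene (X, 3741995 to 3742434), and 136 bp upstream of mRpL41, a mitochondrial ribosomal protein gene (2R, 15217546 to 15217970). Trl, which encodes the GAGA factor, had the peak ranked 6 (3L, 14759310 to 14759746), Gapdh2, a glycolytic gene, that ranked 8 (X, 15867747 to 15868204), and elav, a neuronal RNA-binding protein gene, that ranked 16 (X, 523286 to 523681). The other genes nearest to the 20 highest peaks were hll, cbt, CG4004, CG9663, Pal1, Art3, CG11309, px, Lk6, sbb, CG5611 and PIG-F. Of the 20 summits, 11 were in the promoter class, 7 in introns and 2 intergenic. All 20 peaks were supported by all 3 replicates, and the lowest placed of them in any replicate ranked 43.

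The replicates were compared with each other and with the combined list. Of the 3688 optimal peaks, 85.7% overlapped a top peak of replicate 1 (95% Wilson interval 84.6 to 86.8%), 83.7% of replicate 2 (82.5 to 84.9%) and 72.4% of replicate 3 (70.9 to 73.8%). Random placements gave means of 2.12%, 2.13% and 2.07%, given for scale without a test, because the optimal list was called from the same 3 libraries. Support from all 3 replicates was found for 2072 peaks (56.2%, interval 54.6 to 57.8%; placement mean 1.015%), from 2 replicates for 1124, from 1 for 455 and from none for 37. Support by all 3 fell with signal value, from 93.5% in the highest quintile through 86.9, 62.0 and 28.0% to 10.4% in the lowest. A fall is built into lists of equal length, because the lowest optimal peaks lie at the cut of the pooled ranking. With the whole relaxed lists, 99.8, 99.3 and 86.4% of optimal peaks were found in replicates 1, 2 and 3, and 85.6% in all 3; 501 optimal peaks were absent from the whole list of replicate 3. Over the 1844 highest optimal peaks, 86.2% were supported by all 3.

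**Figure D1:**
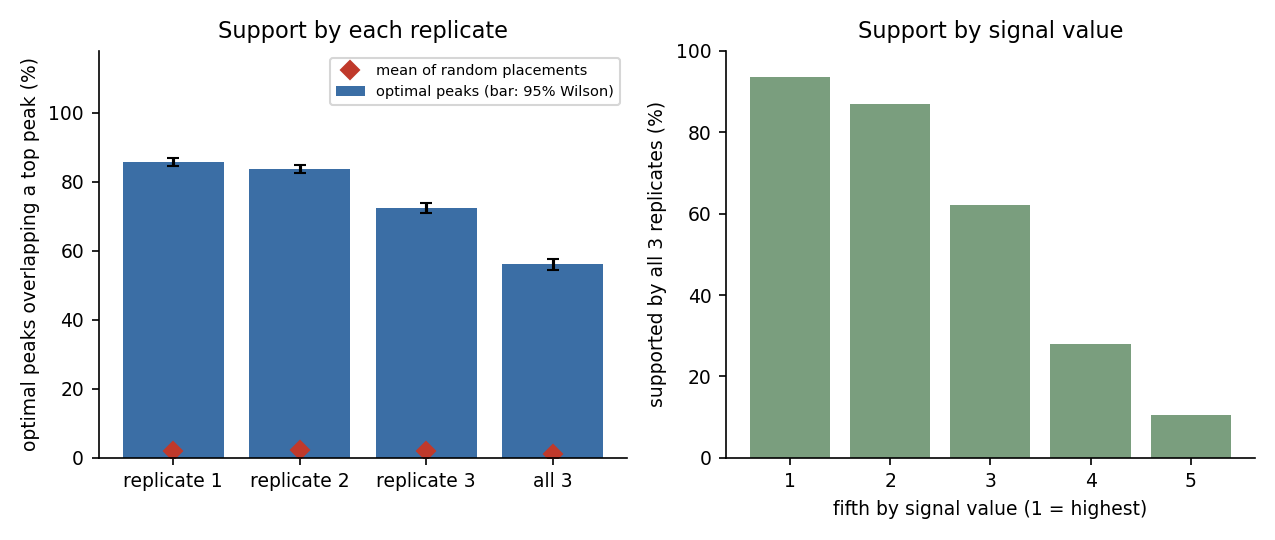
Left, share of the 3688 optimal peaks (%) that overlap one of the 3688 highest peaks of each replicate or of all 3, with 95% Wilson intervals (black bars) and the mean of 1000 random placements (diamonds). Right, share supported by all 3 replicates (%) in each quintile of signal value, which falls from 93.5% to 10.4%. A fall is built into lists of equal length.

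Signal values were correlated across the peaks shared by each pair of replicates. Spearman's rho was 0.763 between replicates 1 and 2 (3655 peaks), 0.709 between 1 and 3 (3180 peaks) and 0.621 between 2 and 3 (3163 peaks), a mean of 0.698 ± 0.0717 (SD over 3 pairs). Pearson's r of log2 signal value was 0.834, 0.768 and 0.703. These values describe peaks within these libraries and carry no test, since peaks are not independent replicates.

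Optimal peaks were concentrated at transcription starts. Of 3688 summits, 1960 (53.1%, interval 51.5 to 54.8%) were in the promoter class, against 24.1% of 25262 relaxed-only summits (odds ratio 3.57, Fisher's exact test, adjusted p = 1.62e-266). The median distance to the nearest start was 399 bp for optimal and 2160 bp for relaxed-only summits. Exons outside promoters held 62 summits (1.68% against 8.67%, odds ratio 0.180, exact adjusted p = 8.74e-67), introns 1193 (32.3% against 46.4%, odds ratio 0.553, exact adjusted p = 7.65e-59) and intergenic sequence 473 (12.8% against 20.8%, odds ratio 0.559, exact adjusted p = 1.16e-32). The 4 classes share 1 total, so the higher promoter share alone lowers the other shares. The intron and intergenic values are thus no separate evidence of depletion. Classes were not compared among summits outside promoters only. Within transcripts, 420 optimal summits lay in annotated 5′ UTRs, 24 in coding sequence (0.651% against 6.49%) and 58 in 3′ UTRs. The promoter share was 62.9% (interval 59.3 to 66.3%) in the highest quintile of signal value and 46.8% (43.2 to 50.4%) in the lowest. Against uniform random positions the odds ratio was 8.68 for promoters and 0.0717 for exons.

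**Figure D2:**
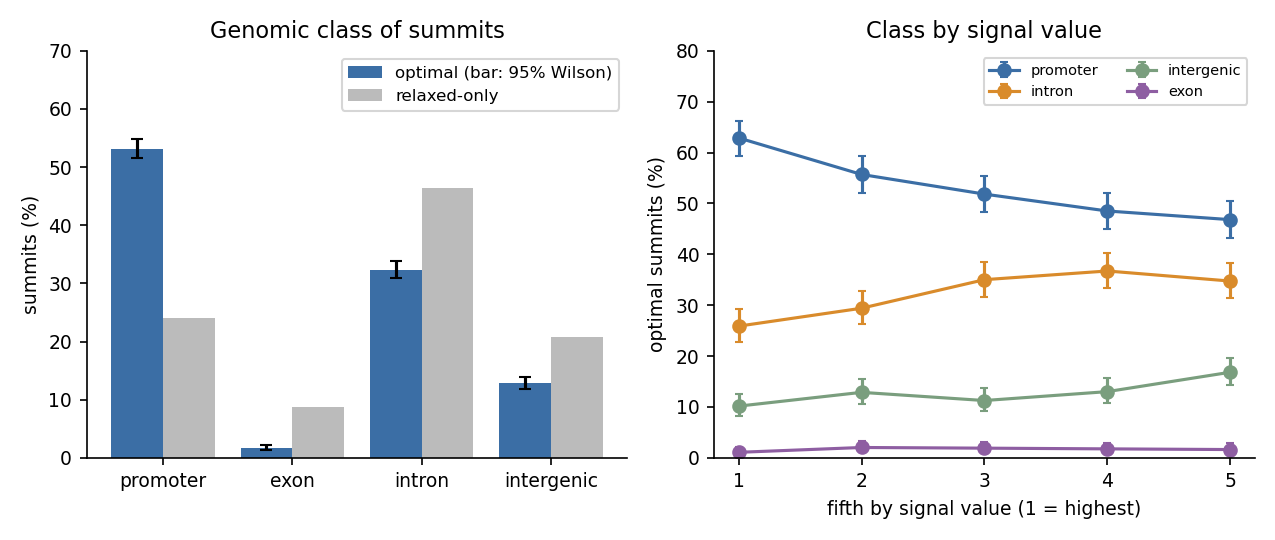
Left, share of summits (%) in each genomic class for optimal peaks (blue, with 95% Wilson intervals) and relaxed-only peaks (grey). Right, share of optimal summits (%) in each class by quintile of signal value, with 95% Wilson intervals; the promoter share goes from 62.9% in the highest quintile to 46.8% in the lowest.

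Cytoplasmic ribosomal protein genes stood out among the 21 gene lists. Of 92 members, 69 were the nearest gene of an optimal peak, against 14.1 expected (4.895 times, adjusted permutation p = 0.0014, from the smallest p that the random lists allow). For 68 of the 69 the best peak was in the promoter class, and the median distance from summit to start was 22 bp. The best peaks had a median rank of 612, with 40 of them among the 737 highest, and 52 of the 69 were supported by all 3 replicates. RpS27 had its summit 8 bp from the start at a peak ranked 21 (3R, 25247342 to 25247704) and RpL7 42 bp at a peak ranked 27 (2L, 10200877 to 10201189). With gene bodies and their surroundings as the assignment the ratio was 2.52. RpL10 and RpL10Aa were among the 23 members without a peak. Proteasome genes, by comparison, had a peak at 3 of 48 members (7.28 expected, adjusted permutation p = 0.214): Rpn11, Rpn6 and Rpn3. Their ratio of 0.412 went to 0.205 without replicate 2. It was 0.673 when only summits within 500 bp of a start counted, and 0.914 with gene bodies and their surroundings.

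Genes of mesoderm and muscle development also had more peaks than matched random lists, 19 of 36 against 9.18 expected (2.07 times, adjusted permutation p = 0.00315). They included Msp300, which encodes a muscle nesprin (rank 157, 2L 5145551 to 5145784), biniou (bin), a visceral mesoderm forkhead gene (rank 220, 3L 6989324 to 6989565), zfh1 (rank 514) and Zasp52, a Z-disc protein gene (rank 525). Only 6 of the 19 best peaks were in the promoter class, and Doc3 and H15 had no peak. The call was not kept when replicate 2 was left out (1.98 times, adjusted permutation p = 0.0532), when only summits within 500 bp of a start counted (1.44 times, adjusted permutation p = 0.754), or with gene bodies and their surroundings as the assignment (1.71 times, adjusted permutation p = 0.0518). Over 9 alternatives the adjusted p went from 0.00105 to 0.754.

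Fewer peaks than expected were found near chemoreceptor genes, which are mostly expressed in sensory neurons, with 4 of 179 against 33.7 expected (adjusted permutation p = 0.0014): Gr89a, Gr93a, Gr93d and Ir48b. The ratio of 0.119 went to 0.0454 without replicate 1, to 0.0780 without replicate 3 and to 0.202 with gene bodies and their surroundings. Replication-dependent histone genes had 0 of 111 (11.1 expected, adjusted permutation p = 0.0014). No relaxed list held a single peak in the histone gene cluster at 2L 21416953 to 21541681, which consists of near-identical repeats, so this value cannot be separated from the handling of reads that map to several places.

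The remaining 17 lists did not pass the threshold after adjustment, and 7 of the 21 had an unadjusted permutation p under 0.05. The count of lists past the threshold rose from 4 to 8 without replicate 3, that is, over optimal peaks supported by replicates 1 and 2. It rose to 7 without matching on length. Other neural homeobox genes had 6 of 50 (13.9 expected, adjusted permutation p = 0.0563), with eyg highest at rank 1399; this list passed, with fewer peaks than expected, under several alternatives (adjusted p of 0.00504 to 0.429 over 9). These were without replicate 2 (0.196 times, adjusted permutation p = 0.0109), without replicate 3 (0.1855 times, adjusted permutation p = 0.00504), over the 1844 highest peaks (0.128 times, adjusted permutation p = 0.016), with matching on relaxed-only peaks (0.427 times, adjusted permutation p = 0.0412) and with peaks supported by all 3 replicates (0.219 times, adjusted permutation p = 0.021). Heat shock genes had 7 of 15 (2.66 expected, adjusted permutation p = 0.0672), led by Hsp83 at rank 23 and stv at rank 433. That list passed with gene bodies and their surroundings (2.16 times, adjusted permutation p = 0.0399), with a range of 0.0399 to 0.485 over 9 alternatives. Notch pathway genes had 10 of 23 (4.99 expected, adjusted permutation p = 0.0888), led by E(spl)m3-HLH at rank 301. That list passed without replicate 1 (2.69 times, adjusted permutation p = 0.0294), 2 (2.88 times, adjusted permutation p = 0.00735) or 3 (2.375 times, adjusted permutation p = 0.03885), without matching on length (2.36 times) and with peaks supported by all 3 replicates (2.91 times), with a range of 0.00735 to 0.837 over 9 alternatives. Signalling genes of the Wnt, Hedgehog, Dpp and EGF pathways had 14 of 32 (8.84 expected, adjusted permutation p = 0.163), led by brk at rank 315 and sty at rank 326, and genes of gut and Malpighian tubule 9 of 19 (4.93 expected, adjusted permutation p = 0.163), led by fkh at rank 91. Both passed without replicate 3 (2.04 times, adjusted permutation p = 0.0287, and 2.39 times, adjusted permutation p = 0.0348), and without matching on length (2.40 and 2.57 times), and the signalling genes also over the 1844 highest peaks (2.21 times). Their adjusted p had ranges over 9 alternatives of 0.00672 to 0.892 and 0.0252 to 0.754.

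The other lists of neural and further tissues did not pass the test either. Neuroblast and proneural genes had 5 of 27 (7.09 expected, adjusted permutation p = 0.651), with numb at rank 245 and brat at rank 294. Neuronal function genes had 4 of 28 (7.33 expected, adjusted permutation p = 0.305), axon guidance and adhesion genes 13 of 38 (11.25 expected, adjusted permutation p = 0.761) with Toll-7 at rank 125, and glial genes 7 of 17 (3.985 expected, adjusted permutation p = 0.265) with moody, a receptor gene of the blood-brain barrier, at rank 58. Hox genes and cofactors had 4 of 10 (2.93 expected, adjusted permutation p = 0.761), namely Abd-B, Antp, hth and lab, and LIM cofactors 2 of 3 (0.633 expected, adjusted permutation p = 0.305), namely Ssdp and Bx, while Chi had none. The ratio of the LIM cofactors was 3.16, and 0 without replicate 1 and 2.05 without replicate 3. Trachea genes had 4 of 14 (3.83 expected, adjusted permutation p = 1), epidermis and cuticle genes 4 of 23 (4.96 expected, adjusted permutation p = 0.949) and appendage and leg patterning genes 7 of 22 (6.57 expected, adjusted permutation p = 1). Blood and fat body genes had 1 of 18 (3.95 expected, adjusted permutation p = 0.265). Their ratio of 0.253 was 0.383 without replicate 1, 0 without replicate 2 or 3, and 0.766 with gene bodies and their surroundings.

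**Figure D3:**
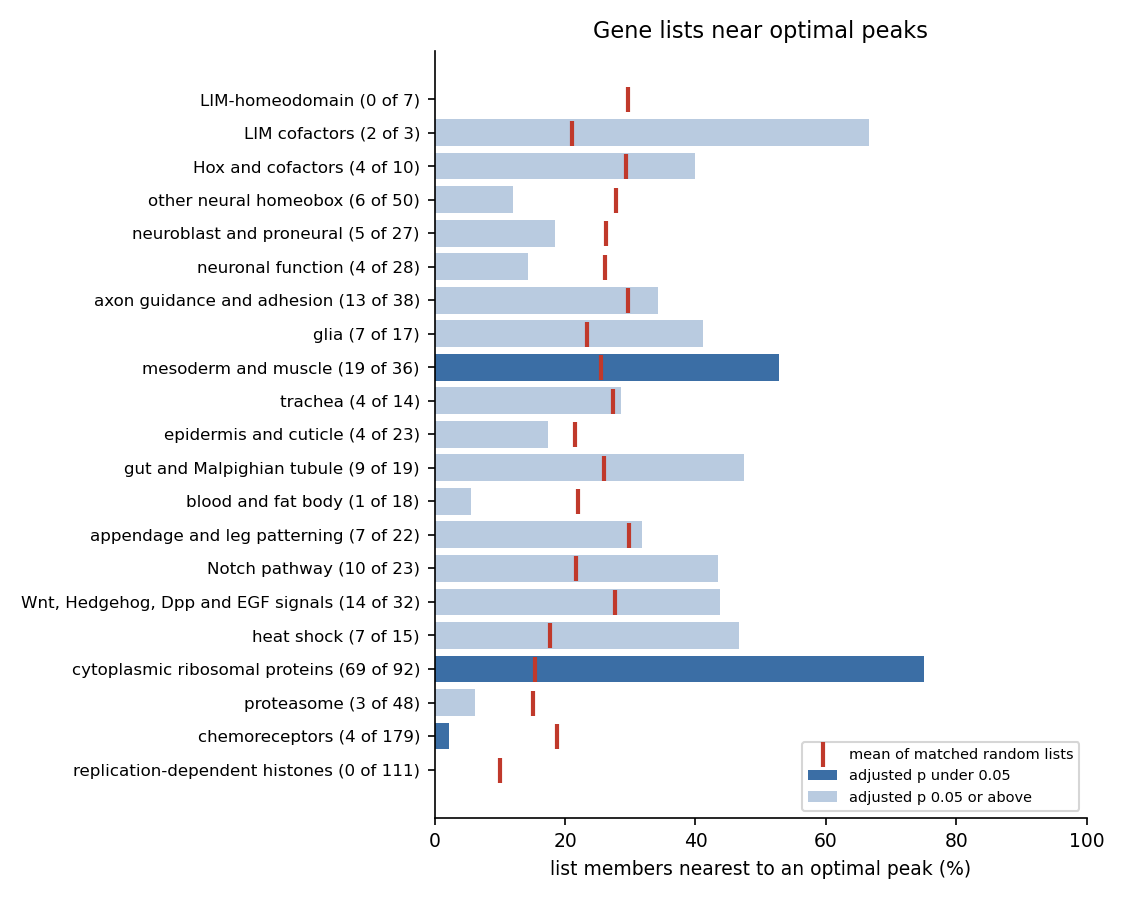
Share of each gene list's members (%) that are nearest to an optimal peak (bars; dark where the adjusted p is under 0.05) with the mean of 10000 matched random lists (red ticks) and counts in the labels. Cytoplasmic ribosomal protein genes reach 69 of 92; histones, also past the threshold, have 0 of 111 and so no bar.

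Peaks were also counted per nearest gene. Of 13945 protein-coding genes, 2561 were nearest to at least 1 optimal peak and 1902 to exactly 1. The genes nearest to the most peaks were shn and tara with 12 each, CHES-1-like with 10, Tlk with 9, and Eip75B, bun and noc with 8 each. The tenth place was shared by 9 genes with 7 peaks each: CG43245, CG43736, CG46385, CG6163, Hr4, NFAT, Raf, chinmo and chn. The best peak of shn ranked 303 (2R, from 11173506) and that of tara 126 (3R, from 16236774). These counts were not tested, not corrected for the length of the surrounding sequence, and include overlapping peaks.

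The sequence TAATTA, the core site of LIM and many other homeodomain proteins, was present within 100 bp of 662 summits (18.0%, interval 16.75 to 19.2%) against 11.7% of flank windows (1.53 times, sign-flip permutation test, adjusted permutation p = 2.4e-05). The ratio was 1.905 at promoter summits and 1.24 at other summits (adjusted permutation p = 0.00946). The longer form TTAATTA had a ratio of 1.48, and of 1.19 outside promoters, where it did not pass (adjusted permutation p = 0.107). The difference between the classes was not tested. Reference sequences made only of A and T had larger ratios: TTTAAA 1.87 times, AATATT 1.88 times and TATATA 1.60 times. In windows of equal GC count, the odds ratio of TAATTA did not pass the threshold (1.055, 95% interval 0.938 to 1.19), nor did that of TATATA (1.07, 0.954 to 1.21). AATATT had an odds ratio of 1.38 (1.24 to 1.53) and TTTAAA 1.30 (1.17 to 1.44).

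The largest ratios were those of core promoter sequences. The DNA replication-related element TATCGATA was present at 3.42% of summits (5.25 times the flanks), Motif 1 (GGTCACACT) at 1.38% (3.64 times) and CAGCNCTG at 4.72% (2.43 times), each with adjusted permutation p = 2.4e-05. At equal GC count their odds ratios were 4.09, 3.88 and 3.22, and against relaxed-only summits the ratios of the first 2 were 2.71 and 2.16. Relaxed-only summits were less often in the promoter class (24.13% against 53.15%), so these 2 ratios cannot be separated from the promoter share. TATCGATA stood at 6.28% of promoter summits (8.48 times the flanks) and at 0.174% of other summits. Outside promoters none of the 3 passed the threshold. There TATCGATA had 0.316, GGTCACACT 0.571 and CAGCNCTG 0.967 times the flanks. In all, 17 of 24 motifs passed the threshold against flanks and 10 at equal GC count. Of the 17, 11 were more frequent and 6 less frequent at summits; of the 10, 8 were above 1 and 2 below, and 8 were among the 17. Among the latter, AGGACA was at 2.55% against 5.44% (0.469 times). For GAGAGAG, the site of the GAGA factor, the outcome depended on the comparison: 0.985 times the flanks at 500 bp (adjusted permutation p = 0.9175), 1.32 times the flanks at 1000 bp (adjusted permutation p = 0.006425) and 0.677 times within 50 bp of the summit (adjusted permutation p = 0.00576). It was 1.36 as an odds ratio at equal GC count, 0.789 times the flanks without replicate 1 (adjusted permutation p = 0.0484) and 0.778 times without replicate 2 (adjusted permutation p = 0.0304), and the adjusted p went from 0.000274 to 0.659 over 8 alternatives. CAGCTG likewise passed in opposite directions, with an odds ratio of 1.48 at equal GC count, but 0.754 times the flanks over the 1844 highest peaks (adjusted permutation p = 0.002695) and 0.835 times without replicate 2 (adjusted permutation p = 0.0325).

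**Figure D4:**
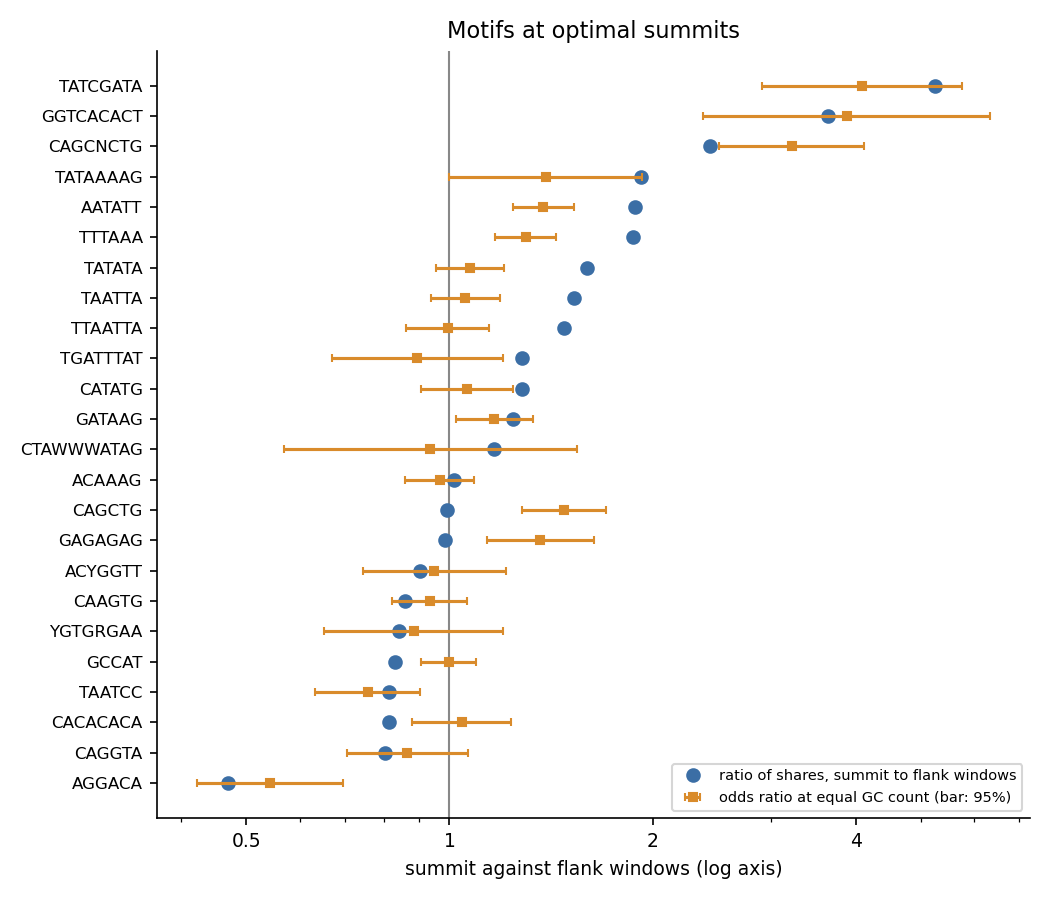
Motifs at optimal summits against flank windows, on a log axis. Circles give the ratio of shares and squares the odds ratio at equal GC count with its 95% interval; TAATTA has a ratio of 1.53 and an odds ratio of 1.055, and TATCGATA a ratio of 5.25 and an odds ratio of 4.09.

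The relation of TAATTA to peak height did not pass the planned test. Its share was 18.4, 20.6, 17.0, 17.3 and 16.4% from the highest to the lowest quintile of signal value, and Spearman's rho across 3688 peaks was 0.0279 (permutation p = 0.0896). The relation passed the threshold within 50 bp of the summit (rho = 0.0463, permutation p = 0.00469) and without replicate 3 (rho = 0.0460, permutation p = 0.0162), and rho was 0.00742 for peaks outside promoters (permutation p = 0.755).

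Optimal peaks were spread over the chromosome arms nearly as relaxed-only peaks were. Arm 2R held 19.7% of optimal and 17.9% of relaxed-only peaks (odds ratio 1.13, exact adjusted p = 0.0253) and X 15.9% and 17.8% (odds ratio 0.873, exact adjusted p = 0.0253). The odds ratios on 2L, 3L, 3R and 4 were 1.02, 1.01, 0.981 and 0.923, none past the threshold. The call on X was lost without replicate 1 (0.919), 2 (0.909) or 3 (0.880), and that on 2R without replicate 1 (1.09) or 2 (1.115). Against genome length per arm, the arms past the threshold were X (0.887, exact adjusted p = 0.0234) and 4 (0.509, exact adjusted p = 0.00977) but not 2R (1.05, exact adjusted p = 0.346). Over the 1844 highest peaks neither X (0.965) nor 2R (1.10) passed. Chromosome 4, with 19 optimal peaks, passed without replicate 2 (odds ratio 0.227, exact adjusted p = 0.01465) and had an odds ratio of 0.317 without replicate 1 (exact adjusted p = 0.0832); over 5 alternatives the adjusted p went from 0.00977 to 0.592. The lists in dm3 held 3593 optimal peaks, with 18.8% on 2L, 19.9% on 2R, 21.5% on 3L, 23.5% on 3R, 0.417% on 4 and 15.9% on X. They come from the same libraries as the dm6 lists, so the shares are given without a test.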

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

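The tests at equal GC count, of constitutively active promoters and of the next 3188 peaks of replicate 3 were chosen only after the result was seen. The dm3 lists hold peaks on heterochromatic and unplaced sequences outside the 6 arms, which no comparison used. The relaxed list of replicate 3 had 275 such peaks, against 31 in replicate 1, 30 in replicate 2 and 32 in the pooled list. They are listed because they lie outside the main measurement; the relaxed lists hold background, the optimal dm3 list had 0 peaks there, and no value shows that they are signal. On the arms in dm6, replicate 3 had 4010 relaxed peaks on X against 5245 and 5543 in replicates 1 and 2, and replicate 1 had 411 on chromosome 4 against 149 and 161. No explanation was tested for these counts.

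Replicate 3 supported fewer optimal peaks than the other libraries, and 501 optimal peaks were absent from its whole list. Of its 500 highest peaks, 499 (99.8%, 95% Wilson interval 98.88 to 99.96%) overlapped a top peak of replicate 1 or 2, against 2131 of its next 3188 (66.8%, interval 65.2 to 68.5%). Such shares were not computed for replicate 1 or 2, so neither value has a baseline. Weaker enrichment of the same sites is consistent with the first value, but a library of another factor or sample stays open: the highest peaks are not where support was low, and strong sites could be shared by many factors. The bound set for excluding another factor, over 75% of the 500 highest peaks, was therefore wrong, as no library of another factor was analysed here. The 7 relaxed peaks at CG4328, against 0 in replicates 1 and 2, and the counts on X and outside the arms also set this library apart, and no biological explanation was tested. Peaks at CG4328 may come from the transgene copy or from binding of the tagged protein, which these lists cannot tell apart.

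TAATTA was more frequent at summits than in flanks. Base composition may account for this: at equal GC count the odds ratio was 1.055 (95% interval 0.938 to 1.19). Recognition of the site by the homeodomain stays open. TAATTA matches lay within 25 bp of the summit in 194 of 751 cases (25.8%), against 1001 of 3571 matches (28.0%) of the A and T reference sequences (odds ratio 0.894, 95% interval 0.744 to 1.07). A small share of peaks bound through TAATTA could be hidden in such a sum.

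Peaks at cytoplasmic ribosomal protein genes invite the explanation that any constitutively active promoter gives a peak. Against that broad form, mitochondrial ribosomal protein and proteasome genes together had a peak at 14 of 121 members, 0.8405 times the matched expectation. This counts against it only as far as these genes are active in the embryos, which was not examined. Inactive members would lower the value. The ratio was 1.17 for the mitochondrial ribosomal protein genes and 0.412 for the proteasome genes. The joint share differed from that of the cytoplasmic genes (Fisher's exact test, p = 1.03e-21). The cytoplasmic and proteasome values were known when this test was chosen, so its p-value describes the difference and is no independent evidence. Most promoter peaks of cytoplasmic ribosomal protein genes had no TAATTA within 100 bp of the summit: the sequence was at 5 of 72 (6.94%). This argues against recruitment through that exact sequence at most of these peaks. Other promoter peaks had it at 354 of 1888 (18.75%, odds ratio 0.3235, 95% interval 0.101 to 0.802). These shares were not compared at equal GC count, so base composition may account for the difference between them. A subset of active promoters stays open. Glycolysis genes without Gapdh2, but with Hex-A (rank 31) and Eno (rank 40), had 2.95 times the matched expectation (adjusted permutation p = 0.0296). Translation factor genes did not pass (1.56 times, adjusted permutation p = 0.1297). Both lists were made after the peaks had been seen, so these values are observations and no support for it. TATCGATA and GGTCACACT had ratios of 5.25 and 3.64 over all summits, but were not counted at ribosomal protein promoter peaks. Very high transcription, which may favour precipitation whatever the tagged protein, and indirect recruitment of CG4328-GFP both stay open, as neither expression nor a GFP-only library was analysed here.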

How the results depend on the processing

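The tests at equal GC count and with peaks supported by all 3 replicates were chosen only after the result was seen. The 4 class results kept their direction and passed the threshold under all 9 alternatives, with odds ratios of 2.555 to 8.68 for promoters, 0.0717 to 0.291 for exons, 0.457 to 0.742 for introns and 0.343 to 0.792 for intergenic sequence. The 4 classes share 1 total, so these are not 4 separate results. Read depth was not known, so its effect could not be examined, and leaving out a replicate also lowers the number of peaks used.

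Support by all 3 replicates was 46.45% with summits within 100 bp, 42.35% with a reciprocal overlap of 50%, 77.5% with replicate lists of 2 times the length, 85.6% with whole lists and 86.2% over the 1844 highest peaks; the pair left without 1 replicate supported 61.0 to 73.9%. With 1 replicate left out only 1 pair remains, so rho then takes the pair values given above, 0.621 to 0.763. The count of arms past the threshold was 0 over the 1844 highest peaks and 0 to 1 with 1 replicate left out. The count of lists was 7 without matching on length and 5 to 8 with 1 replicate left out. The count of motifs was 10 at equal GC count, where TAATTA had an odds ratio of 1.055. The Spearman correlation of TAATTA with signal value was 0.0463 within 50 bp and 0.0189 to 0.0460 with 1 replicate left out.

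The following ratios lay on the other side of 1 from the main value, or spanned it. Arm 3L had 0.926 over the 1844 highest peaks and 0.974 to 1.01 with 1 replicate left out. Among lists, with summits within 500 bp of a start, LIM cofactors and Hox genes had 0, trachea 0.933 and appendages 0.582. Trachea had 0.913 with matching on relaxed-only peaks, neuroblasts 1.01 without matching, and neuronal function 1.20 with gene bodies. With peaks supported by all 3, LIM cofactors had 0 and appendages 0.689; with 1 replicate left out they had 0 to 2.22 and 0.790 to 0.844. Among motifs, against relaxed-only summits, TGATTTAT had 0.921, GAGAGAG 1.35, CAGCTG 1.06, CTAWWWATAG 0.990 and ACAAAG 0.949. At equal GC count TTAATTA had 0.994, TGATTTAT 0.895, GAGAGAG 1.36, CAGCTG 1.48, CTAWWWATAG 0.937, ACAAAG 0.967 and CACACACA 1.04. With flanks 1000 bp away GAGAGAG had 1.32, CAGCTG 1.04 and CACACACA 1.15; ACAAAG had 0.992 within 50 bp. ACYGGTT had 1.03 over the 1844 highest peaks. With 1 replicate left out, CTAWWWATAG had 0.824 to 1.29 and ACYGGTT 0.972 to 1.06. For all values in this part that moved or changed side, the cause was not tested.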

Other observations

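The lists in this part were made after the peaks had been seen, and all tests of them were chosen then. Genes of the Polycomb and trithorax groups, which maintain silent and active states of developmental genes, had a peak at 13 of 26 members against 5.64 expected (2.31 times, adjusted permutation p = 0.012 over the 5 later lists). Trl (rank 6), Psc (rank 22, 2R 12985017 to 12985399), ph-p (rank 25, X 2137654 to 2138126) and ph-d (rank 69) were the highest, and Asx and Pc had none. Glycolysis genes had 7 of 12 against 2.22 expected (3.155 times, adjusted permutation p = 0.012), with Gapdh2 at rank 8, Hex-A at rank 31, Eno at rank 40 and Ldh at rank 165, each 159 to 279 bp upstream of a start; Gapdh1 and Pfk had none. Ecdysone response genes had 9 of 14 against 4.255 expected (2.12 times, adjusted permutation p = 0.0287), with Hr3 at rank 66, Eip75B at rank 167, Hr4 at rank 293 and EcR at rank 527, while Blimp-1 and Eip78C had none. Cytosolic translation factor genes had 14 of 51 (8.99 expected, adjusted permutation p = 0.1297), with eEF1gamma at rank 44 and eIF6 at rank 53. Mitochondrial ribosomal protein genes had 11 of 73 (9.385 expected, adjusted permutation p = 0.6625).

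Some members were already known to have high or many peaks when these lists were made, which favours the lists. The check made for this kept Psc, ph-p, Hex-A and Eno, at ranks 22 to 40. It left out only members nearest to 1 of the 20 highest peaks or among the genes with the most peaks. Without those members, the Polycomb and trithorax group list had 11 of 24 (2.18 times, adjusted permutation p = 0.0296) and glycolysis 6 of 11 (2.95 times, adjusted permutation p = 0.0296), while ecdysone response had 7 of 12 (1.96 times, adjusted permutation p = 0.0944) and no longer passed, and mitochondrial ribosomal protein genes had 10 of 72 (1.08 times). Because these lists were made from the same data, the ratios are observations and not tests of a hypothesis, and other data would be needed for one. They do not tell a property of CG4328 from that of chromatin shared by many precipitated factors.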
